A study of Homo sapiens with 8 samples.

How the data were processed

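Total RNA from BeWo cells was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols, with 8 arrays in 4 groups of 2. The groups were vehicle (control), palmitic acid at 500 uM, TNF-alpha at 10 ng/ml, and both, each for 24 h. The labels number the arrays of a group 1 and 2 and do not say whether they came from separate cultures, so p-values measure the spread between arrays, which may be technical.

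The deposited table gives 1 value per probe set and array, for 54675 probe sets. The deposited values are on a log scale that no label names, and they were taken here as log2; every fold change rests on that reading. The largest range of a probe set over the 8 arrays was 4.62. Each probe set is centred on its own median over the 8 arrays (the largest absolute median is 5e-07), and the array medians lie within 0.0054 of 0. The table therefore holds differences between arrays and no expression level. How the scanner images were summarised and normalised is not given in the sources used here. No signal over background is given with these values, so the number of arrays is the stated limit on precision, and a probe set near background could not be told from a bright one.

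Probe sets were named through the platform's annotation, and symbols were brought up to date through Entrez identifiers with a RefSeq gene table of assembly GRCh38.p14, used for names only. Of the probe sets, 62 were controls, 41091 had 1 gene, 1801 had several genes and 11721 had no gene in the annotation used. The update matched 41043 of the probe sets with 1 gene. Probe sets with several genes or none entered no gene count, and no genome coordinates are given because no build is named with the values. The gene tests covered 19775 genes, of which 10523 had more than 1 probe set.

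The plan fixed before the data were examined assumed expression levels. It called for an intensity trend, a filter on the dimmest probe sets and the brightest probe set per gene, none of which can be computed from centred values. In their place, the probe set with the largest SD over all 8 arrays stood for each gene, chosen without regard to the groups, and no gene was left out. Taking the most variable probe set favours larger changes than the mean over probe sets would give.

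Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit on group means over all 8 arrays, then eBayes; 4 residual degrees of freedom, prior degrees of freedom 3.19). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 19775 genes, with 0.05 as the threshold. Errors are standard errors of the fit, which pools the spread of all 4 groups. The 6 contrasts were each treatment and the combination against control, the combination against each single treatment, and the interaction, which is the combination minus both single treatments plus control. A replicate block was an alternative only.

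The text names EGR1 in every comparison. It also names up to 8 genes per direction with the largest change in the 3 comparisons with control, and up to 5 in the others. These had to pass the threshold, with no overlap between the arrays of the compared groups. Where fewer than 5 genes of a direction passed, the 5 not passing with the smallest p were added and identified as such (the interaction was treated in the same way). From each gene list, the 3 members with the smallest p were eligible as examples. Placeholder symbols were not named. Genes named outside this rule are identified as chosen after their values were seen.

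The 19 gene lists were fixed from textbook knowledge before the data were examined, and 411 of their 445 memberships were measured; the others were not analysed here. Members were counted at the threshold over all genes, and again with p-values adjusted over the list alone. Each list was tested against all other genes with camera, with a preset correlation between genes of 0.01 and again with an estimated one, and adjusted over the 19 lists of a comparison. The lists cover NF-kB feedback and target genes, cytokines and chemokines, immediate early genes, the ATF4 integrated stress response, endoplasmic reticulum chaperones and ERAD, PPAR targets and fatty acid oxidation, cholesterol synthesis, fatty acid synthesis, syncytiotrophoblast and cytotrophoblast genes, placental nutrient transport, the cell cycle, p53 targets and apoptosis, interferon-stimulated genes, NRF2 and oxidative stress, and hypoxia and glycolysis. The remaining lists hold markers of stromal, endothelial, and leukocyte or erythroid cells.

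The fits were tested on simulated values for all 19775 genes with 200 changed. In the simulated palmitic acid comparison, 34% of changes of 0.5 log2 units, 99% of changes of 1 unit and 100% of changes of 2 units were recovered, and 10 unchanged genes were called. In the simulated interaction the shares were 10%, 81% and 100%, with 4 unchanged genes called. Errors were drawn with each gene's SD after eBayes, which pulls it toward a prior SD of 0.104. The measured root mean square SDs between the arrays of a group were 0.122 to 0.162, so these shares may be too high. A simulated list shifted by 0.3 units had a camera adjusted p of 1.04e-26, and no unshifted list was called. These simulated genes varied independently, so the check does not show how the list test behaves when genes are correlated. In the measured data 31 list calls were lost with an estimated correlation and 5 held.

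Alternatives planned before the data were examined and run here were quantile normalisation, median centring of each array, only the 2 groups compared in the fit, the replicate block, leaving out each array in turn, the mean of a gene's probe sets, and each probe set tested alone. For the lists it was the estimated correlation, and for the overlap of the single treatments a minimum change of 1 log2 unit. Alternatives chosen after seeing the data were robust eBayes, array weights, leaving out the genes in the lowest part of the spread (below its median), and the other list and overlap settings. Filters by level could not be run on centred values, and pseudocounts do not apply to values already on a log scale.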

Results

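Gene expression was measured in BeWo cells, a human choriocarcinoma line used as a model of placental trophoblast. After serum was withheld overnight, the cells received vehicle, palmitic acid at 500 uM, TNF-alpha at 10 ng/ml or both for 24 h. Palmitic acid is a saturated fatty acid, and TNF-alpha is an inflammatory cytokine. The series is about EGR1, an immediate early transcription factor, in placental inflammation linked to excess lipid and to maternal obesity. Each of the 4 groups had 2 arrays with 54675 probe sets. Values are log2 differences from each probe set's median, with the log base taken as 2, so no expression level is known.

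The first principal component held 42.9% of the variance and separated the 4 arrays with palmitic acid from the 4 without it. The second held 17.4% and separated the arrays with TNF-alpha from those without. The SD between the 2 arrays of a group, as a root mean square over genes, was 0.12 with palmitic acid, 0.14 with TNF-alpha, 0.15 in the controls and 0.16 with both. The 3' minus 5' value of the actin control probe sets, which tracks RNA quality, was 0.42 and -0.19 on the control arrays, -0.35 and -0.16 with TNF-alpha, 0.10 and 0.13 with palmitic acid, and 0.08 and 0.37 with both. It was 0.24 higher with palmitic acid than without (exact permutation test, two-sided, p = 0.286, n = 4 and 4; adjusted p = 0.571 over 4 control measures).

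Palmitic acid alone, which asks what the fatty acid does in these cells, raised 770 genes and lowered 533 of 19775 (limma, adjusted p under 0.05). EGR1 had the largest rise, by 3.13 ± 0.21 (log2 fold change ± SE, 2 arrays per group), or 8.74-fold (adjusted p = 0.00108). Some genes of fatty acid handling, the oxidative stress response, endoplasmic reticulum chaperones and placental hormones rose with it, while most measured members of these 4 lists did not pass and no list call held with an estimated correlation. The death ligand TNFSF10 and the membrane protein VTCN1 were among the genes that fell. Of the changed genes, 61 rose and 29 fell by over 1 log2 unit.

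After EGR1, the largest rises were in DDAH1, which degrades an inhibitor of nitric oxide synthesis (2.32 ± 0.14), APOA2, an apolipoprotein of high-density lipoprotein (2.11 ± 0.11), and ACSL5, which activates long-chain fatty acids (1.99 ± 0.19). CCN1, a secreted matrix protein, rose by 1.81 ± 0.09 and RCAN1, a calcineurin inhibitor, by 1.61 ± 0.07. UBE2QL1 rose by 1.73 ± 0.14 and LETM2 by 1.72 ± 0.07. The largest falls were in TNFRSF19, a member of the TNF receptor family (-2.04 ± 0.13), VTCN1, a membrane protein that inhibits T cells (-1.72 ± 0.10), the calcium-binding protein S100A4 (-1.63 ± 0.09) and TNFSF10 (-1.55 ± 0.08). RNF145, a ubiquitin ligase of the endoplasmic reticulum, changed by -1.44 ± 0.07, the tyrosine kinase FRK by -1.39 ± 0.18, MYCT1 by -1.33 ± 0.22 and AGXT, a peroxisomal aminotransferase, by -1.28 ± 0.07. The naming rule required both treated arrays to lie beyond both control arrays in each of these genes. The 3 EGR1 probe sets rose by 2.097, 3.12 and 3.13. Probe sets disagreed for LETM2 (-0.06 and 1.72) and RNF145 (-1.44 to 0.05), and 1 of the 4 DDAH1 probe sets passed (0.07 to 2.32). A single probe set also passed for TNFRSF19, of 3 (weakest -0.35), UBE2QL1, of 2 (the other 0.52), and MYCT1, of 2 (the other -0.53).

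**Figure D1:**
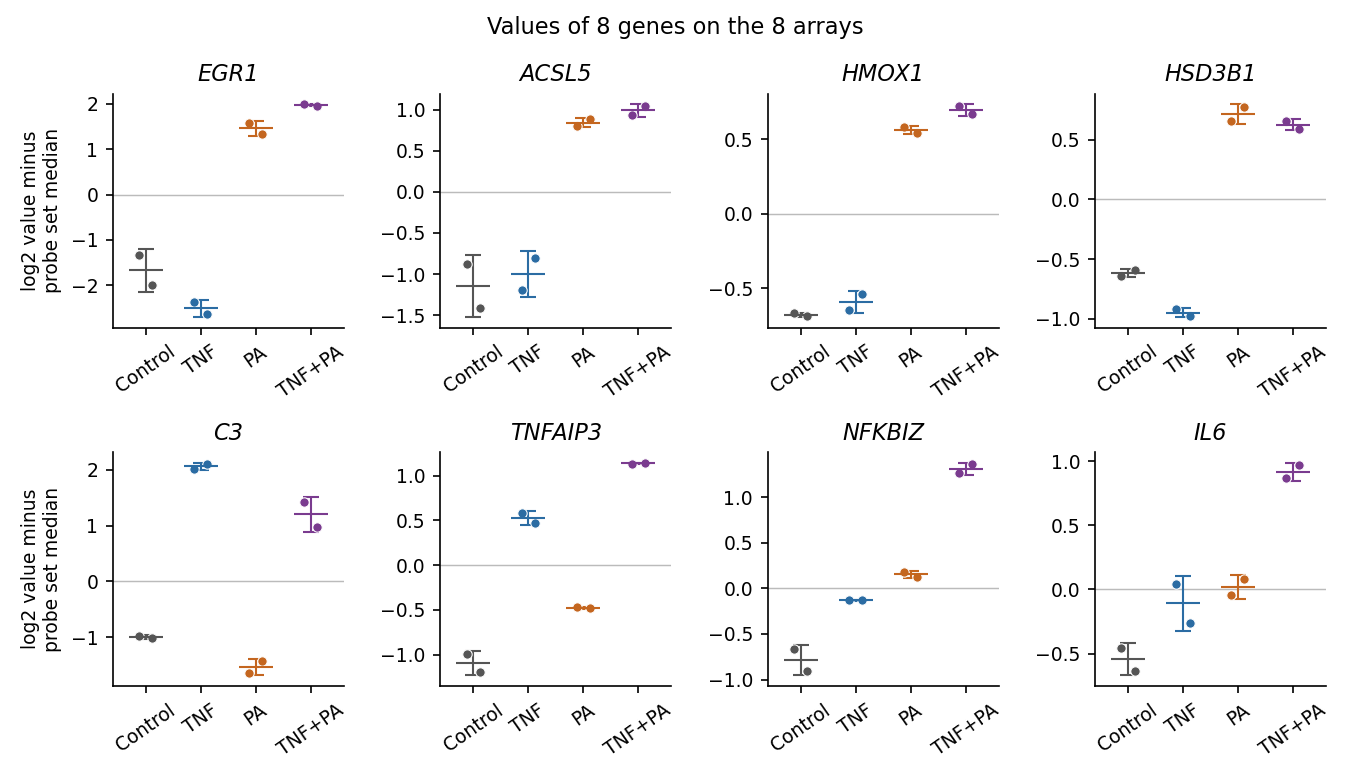
Points are the values of 8 genes on each of the 8 arrays, as log2 value minus the probe set's median (vertical axis), by group (horizontal axis); horizontal marks are group means and bars are SD of 2 arrays. EGR1 averaged -1.67 in the controls, -2.51 with TNF-alpha, 1.46 with palmitic acid and 1.97 with both.

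Immediate early genes, the transcription factors and phosphatases that respond first to growth and stress signals, rose in 13 and fell in 2 of 27 measured members, with 12 not passing (16 and 4 when adjusted over the list alone). EGR1 led, MYC rose by 0.84 ± 0.08, and DUSP5, a phosphatase of ERK, changed by -1.17 ± 0.10. The list stood above other genes (camera adjusted p = 8.19e-07; adjusted p = 0.0668 with an estimated correlation). No list call of this comparison held with an estimated correlation. Without PA replicate 2 the list had 1 rise and 1 fall, without PA replicate 1 it had 3 and 1, and without control replicate 2 it had 7 and 2.

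Among PPAR targets and genes of fatty acid oxidation, 9 rose and 1 fell of 25, with 15 not passing (10 and 1 over the list alone, camera adjusted p = 4.09e-06; adjusted p = 0.0848 with an estimated correlation). ACSL5 and PLIN2, a coat protein of lipid droplets (1.03 ± 0.07), rose, and the receptor gene PPARG changed by -0.74 ± 0.08. NRF2 and oxidative stress genes rose in 7 of 20, with none falling (10 over the list alone, camera adjusted p = 4.09e-06; adjusted p = 0.0668 with an estimated correlation). Its leading members were HMOX1, which degrades haem (1.24 ± 0.08), the quinone reductase NQO1 (1.08 ± 0.08) and SRXN1 (0.74 ± 0.09). Endoplasmic reticulum chaperones and degradation genes rose in 7 of 19, with none falling (9 higher and 1 lower over the list alone, camera adjusted p = 4.60e-05; adjusted p = 0.0668 with an estimated correlation). The translocon subunit SEC61B rose by 1.22 ± 0.12, the co-chaperone DNAJB9 by 1.02 ± 0.11 and HERPUD1 by 0.47 ± 0.07. PLIN2 had probe sets of both signs, and the second probe set did not pass for SEC61B (0.19) or HERPUD1 (0.16). Without 1 array the rises numbered, for fatty acid oxidation, NRF2 and chaperone genes in turn, 1, 2 and 0 without PA replicate 2, 3, 2 and 0 without PA replicate 1, 2, 2 and 2 without control replicate 2 and 3, 4 and 3 without control replicate 1.

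Syncytiotrophoblast and placental hormone genes rose in 8 of 32, with none falling (10 over the list alone, camera adjusted p = 0.00233; adjusted p = 0.181 with an estimated correlation). They included HSD3B1, an enzyme of progesterone synthesis (1.33 ± 0.08), PSG4, a pregnancy-specific glycoprotein (0.90 ± 0.10), and the aromatase CYP19A1 (0.67 ± 0.08), whose probe sets went both ways. The second HSD3B1 probe set stood at 0.36 and did not pass. Cytotrophoblast genes rose in 1 and fell in 4 of 22 (2 and 4 over the list alone), and the list did not pass (camera adjusted p = 0.207); ITGA6 changed by -0.66 ± 0.08, EGFR by -0.59 ± 0.08 and YAP1 by -0.56 ± 0.09. EGFR had 1 of 9 probe sets of the opposite sign. Falls in this list numbered 0 without control replicate 2 or either PA array, where none of these 3 genes passed; EGFR did not pass with the mean of its probe sets either, nor did CYP19A1 and BCL2. Cell cycle genes rose in 6 of 30, with none falling (10 and 1 over the list alone, camera adjusted p = 1.91e-05; adjusted p = 0.144 with an estimated correlation), among them CCNB1 (0.52 ± 0.09) and CDC6 (0.65 ± 0.11). p53 targets and apoptosis genes rose in 4 and fell in 1 of 19 (6 and 1 over the list alone, camera adjusted p = 0.0464; adjusted p = 0.205 with an estimated correlation). BCL2, which blocks apoptosis, rose by 1.13 ± 0.12 on its most variable probe set, while 3 of its 4 probe sets had the opposite sign, and BCL2L11 and PMAIP1, which promote apoptosis, rose by 0.81 ± 0.12 and 0.64 ± 0.11. That last list did not pass without control replicate 1 (0.166), either TNF array (0.0526) or PA replicate 1 (0.182), nor with the mean of a gene's probe sets (0.455). Rises numbered, for placental hormone, cell cycle and p53 genes in turn, 1, 0 and 0 without either PA array, 2, 0 and 1 without control replicate 2 and 6, 0 and 2 without control replicate 1; cell cycle rises were 4 of 30 without either TNF array.

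With palmitic acid alone no list of inflammation passed. NF-kB feedback and target genes rose in 2 of 20 (4 over the list alone), NFKBIZ by 0.94 ± 0.10 and TNFAIP3, an inhibitor of NF-kB signalling, by 0.62 ± 0.09, and the list did not pass (camera adjusted p = 0.0501). It passed without control replicate 2 (0.0270), without PA replicate 2 (0.0166) and with each array's median set to 0 (0.0497). Its rises numbered 0 without either PA array and 1 without control replicate 2. Of 27 cytokines and chemokines, IL6 rose by 0.56 ± 0.12 and TNFSF10 fell (1 and 1 over the list alone, camera adjusted p = 0.952). Interferon-stimulated genes rose in 2 and fell in 2 of 28 (2 and 2 over the list alone, camera adjusted p = 0.555), with USP18, which removes the ubiquitin-like protein ISG15, at -1.05 ± 0.08. Without any 1 array the falls among them numbered 1 and the rises 0 or 1, and IL6 did not pass without any 1 of the control, PA or combination arrays, nor with only the 2 groups in the fit.

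No other list passed. Fatty acid synthesis genes rose in 1 and fell in 4 of 19 (3 and 5 over the list alone, camera adjusted p = 0.456), with ACACB, the mitochondrial acetyl-CoA carboxylase, at 0.95 ± 0.08 with 1 of 7 probe sets opposite, the fatty acid synthase FASN at -0.77 ± 0.08, and ELOVL6 at -0.60 ± 0.07. The second FASN probe set stood at -0.004 and did not pass. No cholesterol synthesis gene of 17 passed (camera adjusted p = 0.850). ATF4 targets rose in 3 and fell in 3 of 24 (7 and 4 over the list alone, camera adjusted p = 0.371), with STC2 at -0.72 ± 0.08. Hypoxia and glycolysis genes rose in 1 and fell in 4 of 22 (3 and 5 over the list alone, 0.371), and nutrient transporters rose in 2 of 23 (3 over the list alone, 0.850). Markers of stromal cells rose in 1 and fell in 2 of 14 (1 and 3 over the list alone, 0.298), those of endothelium rose in 1 and fell in 1 of 12 (2 and 1 over the list alone, 0.884), and those of leukocytes and erythroid cells rose in 1 of 11 (1 over the list alone, 0.850). TAGLN, an actin-binding protein, rose by 1.06 ± 0.09, with probe sets of both signs, and CSF1R, a receptor also found in trophoblast, by 0.50 ± 0.07. Without control replicate 2 or PA replicate 2 no ATF4, hypoxia or transport gene passed. Falls among fatty acid synthesis genes numbered 0 without either PA array, 1 without control replicate 2 and 2 without control replicate 1.

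The count for palmitic acid fell when any 1 array was left out, most without a PA array and least without a combination array. Leaving 1 array in a compared group costs power, so these counts cannot tell lost power from reliance on a particular array. The 1303 genes became 60 without PA replicate 2, 79 without PA replicate 1, 179 without control replicate 2, 509 without control replicate 1 and 801 without either TNF array, and 539 with only the 2 groups in the fit. Of the 16 genes with the largest changes, MYCT1 did not pass without any 1 of the control or PA arrays, FRK without control replicate 2 or either PA array, and ACSL5 without PA replicate 2. Of the 48 passing list examples, 10 passed without PA replicate 2, 11 without PA replicate 1, 19 without control replicate 2 and 31 without control replicate 1.

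TNF-alpha alone, the inflammatory stimulus without the fatty acid, raised 67 genes and lowered 6. The complement component C3 rose most, by 3.06 ± 0.15 or 8.33-fold (adjusted p = 0.000405), followed by the cytokine IL32 at 2.27 ± 0.08. TNFAIP3 and NFKBIA, which inhibit NF-kB, the immunoproteasome subunit PSMB9 and TNF itself were among the genes that rose, and 6 of 20 NF-kB genes passed. EGR1 did not pass, at -0.84 ± 0.21 (adjusted p = 0.219). All 29 genes that changed by over 1 log2 unit rose.

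The other leading rises were in PSMB9, an immunoproteasome subunit (1.93 ± 0.09), OLR1, a receptor for oxidised low-density lipoprotein (1.93 ± 0.09), NPPB, which encodes a natriuretic peptide (1.85 ± 0.09), and LFNG, which modifies Notch receptors (1.75 ± 0.20). ASS1, an enzyme of arginine synthesis, rose by 1.72 ± 0.08 and the sugar transporter SLC2A6 by 1.66 ± 0.12. The 6 genes that fell were the imprinted placental gene PEG10 (-0.87 ± 0.09), MZT1 of the gamma-tubulin complex (-0.85 ± 0.10), AGXT (-0.80 ± 0.07), MYC (-0.64 ± 0.08), TRIM29 (-0.60 ± 0.08) and ALDH6A1 of valine breakdown (-0.57 ± 0.08). A second probe set had the opposite sign for LFNG (-0.04) and for PEG10 (0.13). A single probe set passed for MZT1, TRIM29 and ALDH6A1, of 2, 3 and 5, and the weakest stood at -0.02, -0.001 and -0.02. With the mean of a gene's probe sets LFNG, PEG10, MZT1, TRIM29 and ALDH6A1 did not pass. With each probe set tested alone, 1 of the 3 EGR1 probe sets passed (-0.94 ± 0.09, adjusted p = 0.0160), while the others stood at -0.67 and -0.84.

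NF-kB feedback and target genes rose in 6 of 20, with 14 not passing and none falling (12 over the list alone). The list stood far above other genes (camera adjusted p = 7.12e-16), also with an estimated correlation (adjusted p = 0.0148), the single list call of this comparison that held. TNFAIP3 rose by 1.62 ± 0.09, the NF-kB inhibitor NFKBIA by 1.06 ± 0.08 and the adhesion molecule ICAM1 by 0.87 ± 0.09. A single probe set passed for NFKBIA, of 2, and for ICAM1, of 3, and the weakest stood at 0.13 and 0.11. NF-kB rises numbered 2 without control replicate 2, either TNF array or either PA array, and 3 without control replicate 1 or either combination array. TNF and IL32 both passed without any control, PA or combination array, and TNF did not without either TNF array. Cytokines rose in 2 of 27, IL32 and TNF (1.40 ± 0.14), with 7 over the list alone (camera adjusted p = 0.00112; adjusted p = 0.136 with an estimated correlation). Interferon-stimulated genes rose in 3 of 28 (4 over the list alone, camera adjusted p = 0.00125; adjusted p = 0.326 with an estimated correlation). These 3, PSMB9, PSMB8 (0.71 ± 0.07) and the peptide transporter TAP1 (0.79 ± 0.09), serve antigen processing, and PSMB9 alone passed without any 1 of the control, TNF or PA arrays. ATF4 targets rose in 1 of 24 (4 over the list alone, camera adjusted p = 0.00314; adjusted p = 0.326 with an estimated correlation), the cystine transporter SLC7A11 at 0.64 ± 0.07, which is also the NRF2 member that rose; the ATF4 call was lost without control replicate 1 (0.0822) or TNF replicate 1 (0.0628).

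Immediate early genes rose in 2 and fell in 1 of 27 (5 and 2 over the list alone, camera adjusted p = 0.214), with IER3 at 0.92 ± 0.08, KLF4 at 0.81 ± 0.09 and MYC lower. Without any 1 of the control or TNF arrays, ICAM1, IER3, KLF4, MYC, PMAIP1, CSF1R, SLC7A11, PSMB8 and TAP1 did not pass; without either PA array all of these but IER3 and PMAIP1 did not, and without either combination array MYC did not. With only the 2 groups in the fit none of these 9 passed, nor did NFKBIA and TNF. Among p53 targets PMAIP1 rose by 1.18 ± 0.11, among leukocyte markers CSF1R rose by 0.65 ± 0.07, and PEG10 was the cytotrophoblast gene that fell. No member passed in the lists of chaperones, fatty acid oxidation, cholesterol or fatty acid synthesis, placental hormones, nutrient transport, the cell cycle, hypoxia, or stromal and endothelial markers, and none of these lists passed camera in the fit described. The transporter list passed without control replicate 2 (0.00616) and TNF replicate 1 (0.0272), after quantile normalisation (0.0402) and with the mean of a gene's probe sets (0.0381), the p53 list (0.0361) and the leukocyte list (0.0243) without control replicate 2.

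The TNF-alpha count of 73 genes was 13 without TNF replicate 2, 17 without TNF replicate 1, 18 without control replicate 1, 20 without control replicate 2 and 28 without either PA array. It was 11 with only the 2 groups in the fit and 111 with the mean of a gene's probe sets. C3, IL32, PSMB9, OLR1, NPPB and ASS1 passed without any 1 array; LFNG did not pass without control replicate 1 or any 1 of the TNF, PA and combination arrays, and SLC2A6 did not without TNF replicate 2. Of the 6 genes that fell, none passed without control replicate 1, control replicate 2, TNF replicate 1 or TNF replicate 2, and PEG10 and AGXT passed without the PA or the combination arrays.

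**Figure D2:**
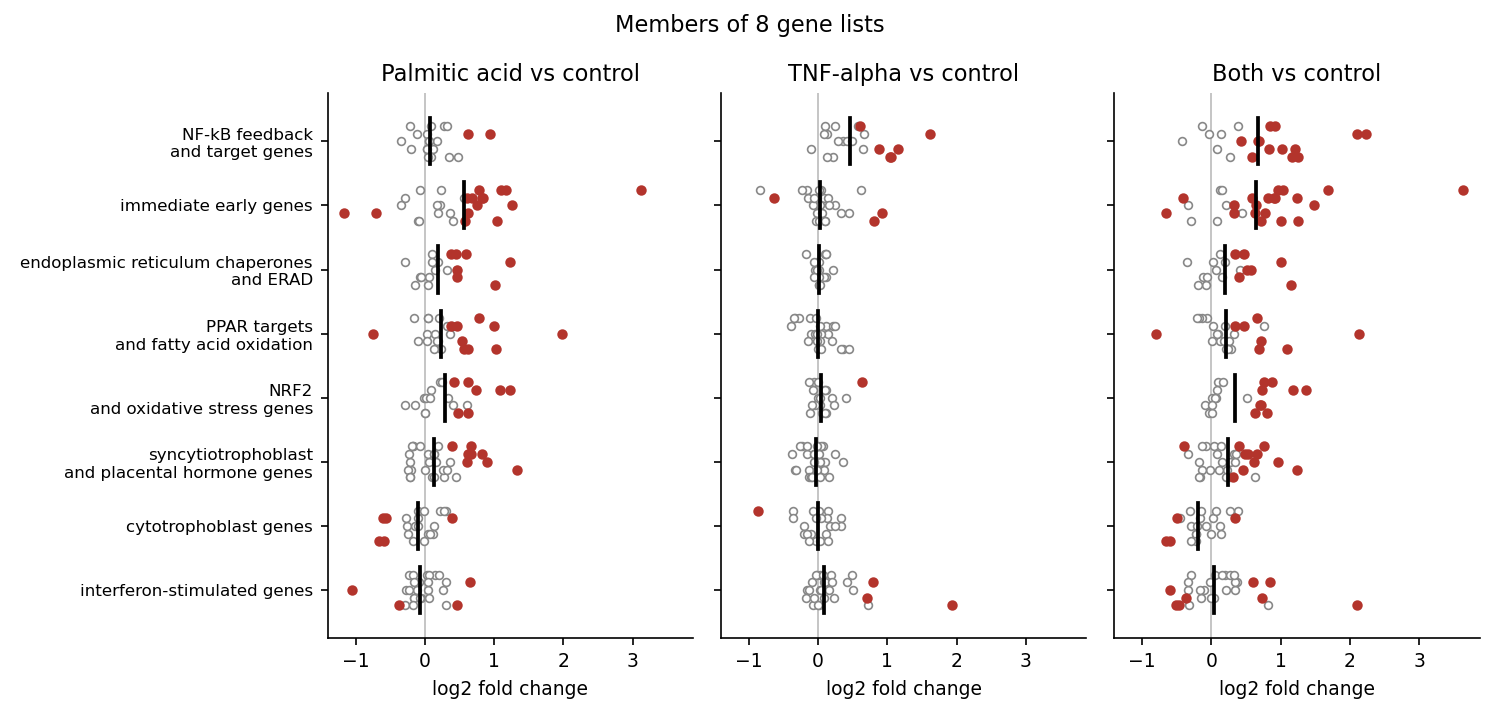
Each point is a member of 1 of 8 gene lists (vertical axis), placed by its log2 fold change against control (horizontal axis) with palmitic acid, TNF-alpha or both; filled points passed an adjusted p of 0.05 in limma, open points did not, and black bars are list medians. NF-kB genes had a median of 0.08 with palmitic acid, 0.46 with TNF-alpha and 0.68 with both, and immediate early genes 0.57, 0.02 and 0.64.

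The combination against control raised 1095 genes and lowered 891. EGR1 rose by 3.64 ± 0.21, or 12.4-fold (adjusted p = 0.000337). Genes that led with palmitic acid stood beside genes that led with TNF-alpha: DDAH1 rose by 2.91 ± 0.14, APOA2 by 2.35 ± 0.11 and CCN1 by 2.32 ± 0.09, and IL32 by 2.29 ± 0.08, TNFAIP3 by 2.23 ± 0.09, C3 by 2.20 ± 0.15 and LFNG by 2.20 ± 0.20. Of the changed genes, 103 rose and 62 fell by over 1 log2 unit.

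The largest falls with both were in VTCN1 (-2.35 ± 0.10), TNFRSF19 (-2.20 ± 0.13), S100A4 (-2.01 ± 0.09), the keratin KRT24 (4.01-fold lower) and AGXT (-1.97 ± 0.07). TRIM9, a ubiquitin ligase, changed by -1.73 ± 0.13, HS6ST2, which sulfates heparan sulfate, by -1.60 ± 0.12 and RNF145 by -1.58 ± 0.07. All 16 genes named for the size of their change passed without any 1 array. DDAH1 had 1 of 4 probe sets with the opposite sign (-0.10). A single probe set passed for DDAH1, for TNFRSF19, of 3 (weakest -0.27), and for LFNG, of 2 (the other 0.17).

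With both treatments, 13 of 20 NF-kB genes rose and none fell (13 higher and 1 lower over the list alone, camera adjusted p = 4.16e-10; adjusted p = 0.0376 with an estimated correlation), with NFKBIZ 4.28-fold higher and NFKBIA at 1.26 ± 0.08. Immediate early genes rose in 18 and fell in 2 of 27 (19 and 3 over the list alone, camera adjusted p = 6.29e-11; adjusted p = 0.0403 with an estimated correlation), with KLF4 at 1.25 ± 0.09 and the stress factor ATF3 at 1.03 ± 0.08. NRF2 genes rose in 9 of 20 (10 over the list alone, camera adjusted p = 5.09e-07; adjusted p = 0.0403 with an estimated correlation), with HMOX1 at 1.37 ± 0.08 and NQO1 at 1.18 ± 0.08; NRF2 members that rose numbered 6 without control replicate 2. These were the 3 list calls that held with an estimated correlation. Cytokines rose in 4 and fell in 1 of 27 (5 and 1 over the list alone, camera adjusted p = 0.137), with TNF at 1.72 ± 0.14 and TNFSF10 at -1.41 ± 0.08.

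Chaperone genes rose in 7 of 19 (9 higher and 1 lower over the list alone, camera adjusted p = 0.000674; adjusted p = 0.0752 with an estimated correlation), with DNAJB9 at 1.15 ± 0.11. Fatty acid oxidation genes rose in 7 and fell in 1 of 25 (9 and 1 over the list alone, 0.000392; adjusted p = 0.143 with an estimated correlation), with ACSL5 at 2.14 ± 0.19 and PLIN2 at 1.09 ± 0.07. Placental hormone genes rose in 10 and fell in 1 of 32 (12 and 1 over the list alone, 0.000392; adjusted p = 0.143 with an estimated correlation), with HSD3B1 at 1.24 ± 0.08. Cytotrophoblast genes rose in 1 and fell in 3 of 22 (1 and 5 over the list alone, 0.0275; adjusted p = 0.222 with an estimated correlation), with EGFR at -0.66 ± 0.08, a call lost without TNF+PA replicate 2 (0.0839). Cell cycle genes rose in 5 and fell in 1 of 30 (11 and 2 over the list alone, 0.0109; adjusted p = 0.240 with an estimated correlation), and CDC6 led at 0.77 ± 0.11. Rises without control replicate 2 numbered 3 for chaperones, 4 for fatty acid oxidation, 5 for placental hormones and 0 for the cell cycle; without control replicate 1 hormones had 6 and the cell cycle 3. Without TNF+PA replicate 1 chaperones had 3 and hormones 5, and without TNF+PA replicate 2 chaperones had 3, hormones 5 and the cell cycle 2.

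p53 targets and apoptosis genes rose in 7 of 19 (8 higher and 2 lower over the list alone, camera adjusted p = 0.0275; adjusted p = 0.204 with an estimated correlation), led by PMAIP1 at 1.72 ± 0.11; the call was lost without control replicate 1 (0.0698) or TNF+PA replicate 2 (0.0502), and with the mean of a gene's probe sets (0.105). ATF4 targets rose in 7 and fell in 2 of 24 (11 and 4 over the list alone, 0.0275; adjusted p = 0.399 with an estimated correlation), with DDIT3, a factor of the stress response, at 0.62 ± 0.08; this call was lost without control replicate 1 (0.111) or TNF+PA replicate 1 (0.0573). Hypoxia and glycolysis genes rose in 1 and fell in 4 of 22 (2 and 7 over the list alone, 0.0452; adjusted p = 0.204 with an estimated correlation), with the aldolase ALDOC at -0.71 ± 0.09. That call was lost without control replicate 1 (0.0915), either PA array (0.0551), TNF+PA replicate 1 (0.0841) or TNF+PA replicate 2 (0.0627), and with the mean of a gene's probe sets (0.177). The p53 rises numbered 3 without control replicate 2 and 4 without control replicate 1, either PA array or TNF+PA replicate 2. The ATF4 rises numbered 3 without control replicate 2 and 4 without either combination array. The hypoxia falls numbered 1 without control replicate 2 and 2 without control replicate 1 or TNF+PA replicate 2. Interferon-stimulated genes rose in 4, PSMB9 among them, and fell in 4 of 28 (6 and 5 over the list alone, 0.464); falls numbered 1 without any 1 of the control or combination arrays and 2 without either PA array. Fatty acid synthesis genes rose in 2 and fell in 3 of 19, and no cholesterol gene of 17 passed. Transporters rose in 3 and fell in 2 of 23 (0 and 0 without control replicate 2, 1 and 1 without control replicate 1, 2 and 0 without either combination array, 3 and 1 without any 1 of the others), stromal markers 1 and 1 of 14, endothelial markers 1 and 1 of 12, and leukocyte markers 1 and 0 of 11; none of these lists passed.

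The 1986 genes changed by the combination became 585 without control replicate 2, 963 without TNF+PA replicate 1, 992 without control replicate 1, 1015 without TNF+PA replicate 2 and 1257 without either PA array. With only the 2 groups in the fit there were 546.

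Palmitic acid added to TNF-alpha, the comparison of the combination with TNF-alpha alone, raised 970 genes and lowered 842. EGR1 rose by 4.48 ± 0.21, or 22.3-fold (adjusted p = 0.000273). DDAH1 (2.28 ± 0.14), the muscle actin ACTA1 (2.23 ± 0.09), APOA2 (3.99-fold) and ACSL5 (1.99 ± 0.19) followed. TNFRSF19 fell most (-2.72 ± 0.13), then VTCN1 (-1.95 ± 0.10), TNFSF10 (-1.81 ± 0.08), the receptor GPRC5A (-1.77 ± 0.15) and the actin regulator PHACTR1 (-1.62 ± 0.20). The other probe sets of DDAH1, TNFRSF19 and PHACTR1 included some of the opposite sign, and PHACTR1 did not pass with only the 2 groups in the fit.

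In this comparison immediate early genes rose in 15 and fell in 5 of 27 (20 and 5 over the list alone, camera adjusted p = 1.60e-07; adjusted p = 0.0907 with an estimated correlation), with MYC at 1.54 ± 0.08. NRF2 genes rose in 8 of 20 (8 over the list alone, 1.17e-05; adjusted p = 0.0907 with an estimated correlation) and placental hormone genes in 10 of 32 (11 over the list alone, 1.17e-05; adjusted p = 0.115 with an estimated correlation), HMOX1 by 1.29 ± 0.08 and HSD3B1 by 1.57 ± 0.08. Fatty acid oxidation genes rose in 7 and fell in 1 of 25 (9 and 1 over the list alone, 0.000434; adjusted p = 0.121 with an estimated correlation), and cell cycle genes rose in 7 and fell in 2 of 30 (12 and 2 over the list alone, 0.000434; adjusted p = 0.150 with an estimated correlation). Chaperones rose in 6 of 19 (9 and 1 over the list alone, 0.00170; adjusted p = 0.115 with an estimated correlation). NF-kB genes rose in 3 and fell in 1 of 20 (3 and 1 over the list alone, 0.00908; adjusted p = 0.121 with an estimated correlation), NFKBIZ by 1.44 ± 0.10. Hypoxia genes rose in 1 and fell in 4 of 22 (2 and 6 over the list alone, 0.0110; adjusted p = 0.121 with an estimated correlation). Of the cytokines, IL6 rose by 1.02 ± 0.12 and TNFSF10 fell, and 5 interferon-stimulated genes fell, USP18 by -1.09 ± 0.08, without a call for either list. Cytotrophoblast genes rose in 1 and fell in 5 of 22 without a call (camera adjusted p = 0.125). That list passed, lower, with the mean of a gene's probe sets (0.0232). The p53 list, with 6 rising and 3 falling of 19, and the ATF4 list, with 3 and 4 of 24, did not pass. Falls of interferon-stimulated genes numbered 1 without any 1 of the 8 arrays. NF-kB rises numbered 1 without any 1 of the TNF or combination arrays and 2 without any other; hypoxia falls numbered 0 without TNF replicate 1, TNF replicate 2 or TNF+PA replicate 2, 1 without TNF+PA replicate 1, 3 without either PA array and 5 without either control array. Without TNF replicate 1 the rises of immediate early, hormone, chaperone and cell cycle genes numbered 10, 4, 2 and 2, and without TNF replicate 2 they numbered 11, 4, 2 and 3. Without TNF+PA replicate 1 they numbered 10, 5, 2 and 4, without TNF+PA replicate 2 10, 6, 3 and 3, and without either PA array 11, 8, 4 and 4; NRF2 rises were 5 without TNF replicate 1. The count of 1812 genes became 364 without TNF replicate 1, 377 without TNF replicate 2, 666 without TNF+PA replicate 1, 706 without TNF+PA replicate 2, 931 without either PA array and 218 with only the 2 groups in the fit.

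TNF-alpha added to palmitic acid raised 46 genes and lowered 3. C3 rose by 2.74 ± 0.15, or 6.69-fold (adjusted p = 0.00105), IL32 by 2.16 ± 0.08, SLC2A6 by 1.93 ± 0.12, LFNG by 1.92 ± 0.20 and LRRC32, which holds latent TGF-beta at the cell surface, by 1.86 ± 0.12. The 3 genes that fell were GABBR2, a subunit of a GABA receptor (-0.72 ± 0.08), AGXT (-0.69 ± 0.07) and XYLT1, which starts proteoglycan chains (-0.55 ± 0.07). The next genes by p did not pass: PLCD4 at -0.74 ± 0.10, ZNF160 at -0.66 ± 0.09, TRIM9 at -0.85 ± 0.13, DENND2A at -0.55 ± 0.08 and DLX4 at -0.49 ± 0.07. EGR1 stood at 0.51 ± 0.21 and did not pass (adjusted p = 0.469).

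NF-kB genes rose in 6 of 20 (12 over the list alone, camera adjusted p = 6.86e-16; adjusted p = 0.0147 with an estimated correlation), TNFAIP3 by 1.61 ± 0.09 and NFKBIA by 1.20 ± 0.08, and this was the single list call that held with an estimated correlation. NF-kB rises numbered 2 without any 1 of the PA or combination arrays and 4 of 20 without either TNF array. Immediate early genes rose in 1 of 27, IER3 at 1.04 ± 0.08 (5 over the list alone, 7.48e-05; adjusted p = 0.132 with an estimated correlation), and in none without either PA array or TNF+PA replicate 1. Cytokines rose in 2 of 27, IL32 and TNF (4 over the list alone, 0.00292; adjusted p = 0.132 with an estimated correlation), a call lost without PA replicate 1 (0.0543); TNF did not pass without any 1 of the TNF, PA or combination arrays, which left 1 rise. Interferon-stimulated genes rose in 3 of 28, PSMB9, PSMB8 and TAP1 (5 over the list alone, 0.0127; adjusted p = 0.364 with an estimated correlation), a call lost without PA replicate 1 (0.0715) or TNF+PA replicate 1 (0.0752); PSMB8 and TAP1 did not pass without any 1 of the 8 arrays. ATF4 targets (0.00585; adjusted p = 0.364 with an estimated correlation; 3 over the list alone) and NRF2 genes (0.0364; adjusted p = 0.330 with an estimated correlation; 1 over the list alone) stood higher with no member passing. The NRF2 call was lost without PA replicate 1 (0.0543), PA replicate 2 (0.168), TNF+PA replicate 1 (0.0752) or TNF+PA replicate 2 (0.116), after quantile normalisation (0.139) and with the mean of a gene's probe sets (0.0735). The count of 49 genes became 13 without PA replicate 1, 14 without PA replicate 2, 16 without TNF+PA replicate 1, 17 without TNF+PA replicate 2, 27 without either TNF array and 32 without either control array, 18 with only the 2 groups in the fit and 78 with the mean of a gene's probe sets. GABBR2, AGXT and XYLT1 did not pass without any 1 of the 8 arrays, and LFNG did not without any 1 of the PA or combination arrays.

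**Figure D3:**
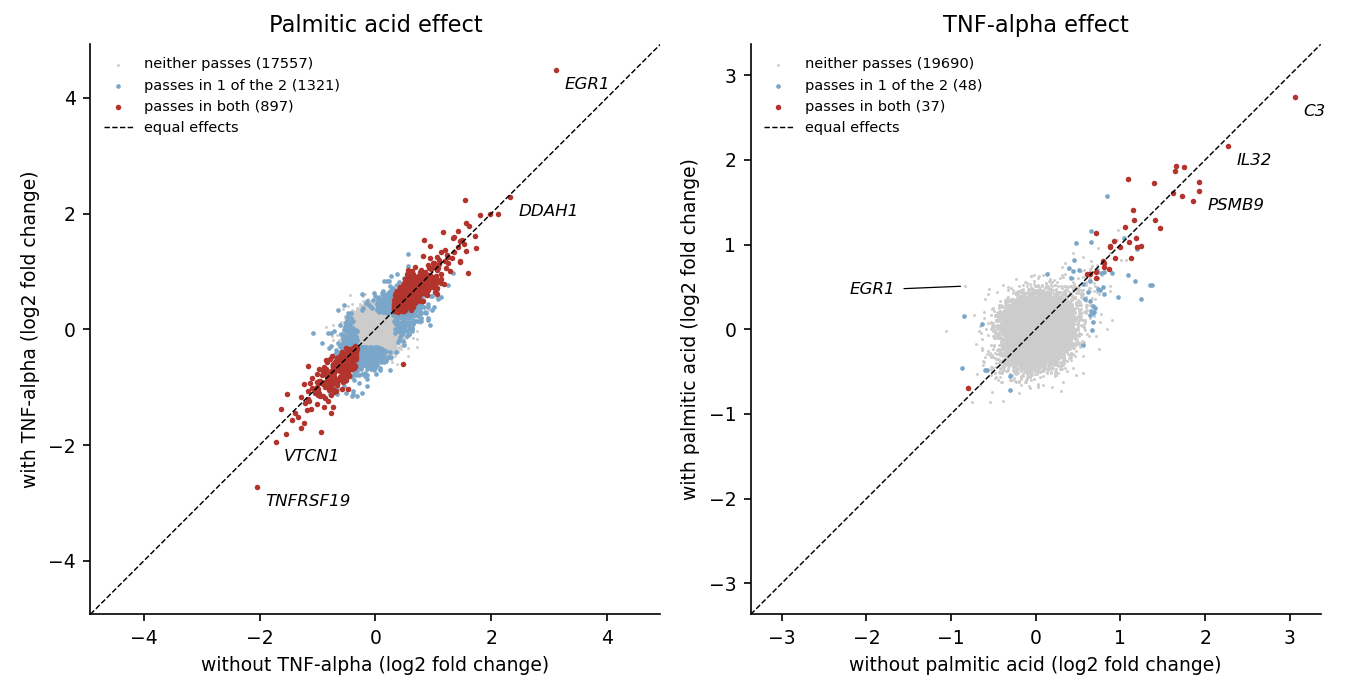
Each point is 1 of 19775 genes; the left panel sets the log2 fold change by palmitic acid without TNF-alpha (horizontal axis) against that with TNF-alpha (vertical axis), the right panel does so for TNF-alpha without and with palmitic acid, and the dashed line marks equal effects. Red points, 897 on the left and 37 on the right, passed in both comparisons, blue points in 1 of the 2 and grey points in neither.

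In most genes called for a treatment alone, its effect kept its direction when the other treatment was present. Of the 1303 genes changed by palmitic acid alone, 96.9% had the same sign when it was added to TNF-alpha, in comparisons that share no array. Genes called in both numbered 897, of which 523 rose and 373 fell in both, against 37.8 and 22.7 for independent lists. The exception, chosen here after its values were seen, was LINC00312 (0.48 and -0.60). Of the 73 genes changed by TNF-alpha alone, 94.5% had the same sign when it was added to palmitic acid; 37 were called in both, 36 rising and 1, AGXT, falling, against 0.156 and 0.00091 for independent lists. The slope of the second effect on the first, across the called genes, was 0.907 for palmitic acid and 0.850 for TNF-alpha, values that selection of the called genes in the first comparison lowers. Over all genes, Pearson's r between the effects without and with the other treatment was 0.640 for palmitic acid and 0.277 for TNF-alpha. Spearman's correlation was 0.492 for palmitic acid and 0.138 for TNF-alpha. The similarity therefore holds for the called genes, and was weaker over all genes, most of all for TNF-alpha.

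No gene departed from additive effects in the interaction test (limma, adjusted p under 0.05), and 1442 had an unadjusted p under 0.05; the smallest adjusted p was 0.675. EGR1 had an interaction of 1.35 ± 0.30 and did not pass. The smallest p-values among positive interactions, none passing, belonged to MZT1 (1.01 ± 0.14), ZNF385D (0.96 ± 0.15), MYC (0.70 ± 0.11), CTXND1 (0.68 ± 0.12) and ACVR1B (0.59 ± 0.10). Among negative ones they belonged to NKAIN4 (-0.75 ± 0.11), MYORG (-0.74 ± 0.12), CHRNA10 (-0.65 ± 0.11), ZNF160 (-0.75 ± 0.13) and PHF7 (-0.59 ± 0.11). No list passed; immediate early genes had a camera adjusted p of 0.254, and 0.0147 with the mean of a gene's probe sets. Adjusted over the list alone, 2 immediate early genes were higher and 1 lower, and 1 leukocyte marker was lower.

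Palmitic acid and TNF-alpha, each against the same controls, called 28 genes in common. Both raised 13 of them, against 2.61 for independent lists, and both lowered 4, against 0.162, while 11 moved in opposite directions, against 2.04. TNFAIP3, KLF4, PMAIP1, PSMB9 and NPPB rose with either treatment. MYC rose with palmitic acid and fell with TNF-alpha, and IER3, an early response gene, did the reverse (-0.71 ± 0.08 and 0.92 ± 0.08). Across genes, which are not independent, Pearson's r was 0.256, while unchanged groups sharing these controls gave 0.500 (0.484 to 0.515 in 100 draws). The covariance was 0.0119 against 0.00814 simulated, a difference of 0.00379. Errors in the draws used each gene's SD after eBayes, pooled over the 4 groups, rather than the measured spread of the controls (root mean square SD 0.145). The simulated covariance may therefore be too low, and the difference does not show covariance beyond the shared controls. The 2 controls could not be split, so part of the shared calls may come from them, and part from the pooled spread that both calls use. The 28 genes became 3 without control replicate 1, 5 without control replicate 2, 5 without TNF replicate 1, 4 without TNF replicate 2 and 3 without either PA array.

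Median, mean and test of a list differed in sign only where the list did not pass. This held for nutrient transport and leukocyte markers with palmitic acid, fatty acid oxidation and cholesterol synthesis with TNF-alpha, cholesterol synthesis, stromal and endothelial markers with both, cholesterol synthesis and endothelial markers for TNF-alpha added to palmitic acid, and the ATF4, cholesterol and cytotrophoblast lists in the interaction.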

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

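The test that each EGR1 probe set rises, the test of array loss, the RNA quality test, the spike-in test and the test of interaction power were chosen after the results were seen; the test of replicate gaps was not.

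Probe sets without a gene name in the annotation used, which no comparison above counts, also responded. With palmitic acid 212 of these 11721 probe sets passed, with TNF-alpha 14, and with both 332 (limma, each probe set tested alone).

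Some genes had effects of palmitic acid that differed with and without TNF-alpha when the interaction was adjusted over their list alone, although none passed over all genes. EGR1 (1.35, adjusted p = 0.0223) and MYC (0.70, adjusted p = 0.0117) had larger estimated rises with palmitic acid when TNF-alpha was present, from a lower TNF-alpha mean. For EGR1 that lower mean did not pass against control on the probe set used (limma, adjusted p = 0.219). KLF6, a zinc-finger factor, had an interaction of -0.71 (adjusted p = 0.0223) and the leukocyte list's CSF1R one of -0.43 (adjusted p = 0.0404), while only 2 of the 5 KLF6 probe sets had that sign. The adjusted p over all genes was 0.675 in each.

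Palmitic acid changed more genes than TNF-alpha, 1303 against 73. The order of the 2 counts held without any 1 array, while the size of the difference varied with the array left out. Each such fit also loses power. The lowest ratio of the counts over the 8 settings that each leave out 1 array was 2.14, without PA replicate 2. It was 2.82 without PA replicate 1. RNA quality as the source cannot be excluded. The 2 control arrays differed by 0.60 in the actin 3' minus 5' value. Along the palmitic acid effect they lay apart by 0.0783 of the distance between palmitic acid and control. The 218 genes of that effect were called on the TNF-alpha and combination arrays alone, so neither group took part in the choice. The GAPDH 3' minus 5' value did not set the controls apart (-0.0013 and 0.0041), so 1 pair of arrays that differed on actin alone cannot decide. That value was highest on the combination arrays (0.062 and 0.055), which took part in choosing the genes. A processing batch that followed palmitic acid cannot be told apart from the treatment, because no batch is given. Hybridisation spike-ins differed by -0.0384 between arrays with and without palmitic acid (exact permutation test, two-sided, p = 0.486) and overlapped. That test pooled palmitic acid alone with the combination. The arrays with palmitic acid alone were the lowest of all 8 (-0.098 and -0.085) and did not overlap the controls (-0.001 and 0.054). The TNF-alpha arrays stood at -0.039 and 0.078, and the combination arrays at 0.010 and 0.110. A larger response to this dose of fatty acid than to this dose of cytokine stays open, as a hypothesis.

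Of 27 immediate early genes, 13 rose and 2 fell 24 h after palmitic acid was added, a list call lost with an estimated correlation (adjusted p = 0.0668); 1 rose without PA replicate 2. The largest gap between the 2 arrays of a group in the list's mean was 0.0868 of the palmitic acid effect on it. That gap is under the bound set beforehand, yet handling of the dishes cannot be told apart from the treatment, since the labels do not say that the 2 arrays of a group came from separate dishes. A stray transcript on 1 EGR1 probe set is argued against by the lowest of the 3 probe sets, which still rose by 2.097. A lasting response to the fatty acid is a hypothesis that these values leave open.

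The interaction test called no gene. In simulation 81% of interactions of 1 log2 unit and 10% of those of 0.5 were recovered, with 200 changed genes, which eases the adjustment for each. The simulated errors also used SDs after eBayes, so these shares may be too high. In the measured values EGR1 (1.35) and MZT1 (1.01) exceeded 1 unit and did not pass, so the simulated share does not show that a few large interactions would have been called. Effects that add cannot be told apart from interactions missed with 2 arrays per group.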

How the results depend on the processing

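Robust eBayes, array weights, the spread filter, and the list and overlap settings other than the estimated correlation and the 1-unit minimum were chosen after seeing the data. Counts of called genes moved by over 1.5 times under 4 kinds of setting, besides the loss of 1 array. With only the 2 groups in the fit, which has fewer arrays to estimate the spread, they were 539 for palmitic acid, 11 for TNF-alpha, 546 for both, 218 and 18 for palmitic acid and TNF-alpha added to the other, and 3 for the overlap. With the mean of a gene's probe sets they were 111 for TNF-alpha, 78 for TNF-alpha added to palmitic acid and 48 for the overlap; the cause was not tested. With a minimum of 1 log2 unit the overlap held 1 gene. With the replicate block the counts were 718 for palmitic acid, 28 for TNF-alpha, 1201 and 28 for palmitic acid and TNF-alpha added to the other, and 10 for the overlap; under it the hypoxia list lost its call with both treatments (0.0518), and the NF-kB list with palmitic acid (0.0416) and the transporter list with TNF-alpha (0.0486) gained one. The replicate numbers share no sign of pairing: correlations of the deviations of equal numbers between groups ran from -0.19 to 0.19.

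Leaving out 1 array, after which the lone array of a group is assumed to vary like the others, gave 60 to 1125 genes for palmitic acid, 13 to 49 for TNF-alpha, 585 to 1492 for both, 364 to 1366 for palmitic acid added to TNF-alpha, 13 to 32 for TNF-alpha added to palmitic acid and 3 to 19 for the overlap. The interaction count was 0 in every setting run. Quantile normalisation, median centring, each probe set alone, robust eBayes, array weights and the spread filter left every count within 1.5 times. The weights were equal for the 2 arrays of each group, so that setting could not mark down a single poor array.

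Over all settings, the named genes gave 3519 results with the same direction and side of the threshold, 511 with the same direction and no longer passing, 5 newly passing and none with another direction. Lists that passed kept their call in 408 results and lost it in 60, with no change of direction. Filters by level and other pseudocounts were not run, since the values are centred logs. The values carry no signal over background, so genes near background could not be set apart.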

Other observations

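The tests of 3 further lists were written after the first gene results were seen and before their own results; genes already named were left out of each list. All 3 lists were drawn up after seeing the data, and their p-values are from camera in limma.

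Palmitic acid raised several genes of the actin cytoskeleton outside the fixed lists. Of 21 genes of the serum response factor and actin group, 4 rose and none fell: ACTG2 (0.51 ± 0.08), an enteric actin, MYL9 (0.58 ± 0.11), a myosin light chain, and the tropomyosins TPM2 (0.43) and TPM4 (0.38). The group stood above other genes (p = 3.67e-05, adjusted p = 0.00011 over the 3 lists), a call lost with an estimated correlation (adjusted p = 0.0791). The same held for palmitic acid added to TNF-alpha (adjusted p = 2.70e-05; adjusted p = 0.0627 with an estimated correlation), and TNF-alpha alone gave no call (adjusted p = 0.811). A candidate explanation is activity of serum response factor, which also drives EGR1, and it remains a hypothesis found and tested on the same arrays.

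Antigen processing genes other than PSMB8, PSMB9 and TAP1 stood higher with TNF-alpha as a group of 16 (p = 0.00019, adjusted p = 0.000571; adjusted p = 0.0483 with an estimated correlation). TAPBP, which loads peptides on class I molecules, was the 1 member that passed (0.77 ± 0.09); TAP2 did not, at 0.50 ± 0.08. For TNF-alpha added to palmitic acid no member passed, and the group's call (adjusted p = 0.0139) was lost with an estimated correlation (adjusted p = 0.116). The combination against control gave no call (adjusted p = 0.162). The group includes CALR, which also belongs to the fixed chaperone list. With palmitic acid TAP2 (0.61 ± 0.08) and B2M (0.64 ± 0.09) rose while the group as a whole did not stand apart. A wider presentation response to TNF-alpha stays a hypothesis.

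Autophagy and lysosome genes were tested because SQSTM1 was seen to rise with palmitic acid. The group of 26 did not stand apart from other genes (p = 0.584, lower; p = 0.574 with an estimated correlation). ULK1, a kinase that starts autophagy, was the 1 member that fell (-0.47 ± 0.09), and none rose.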
